A study of Homo sapiens with 12 samples.

How the data were processed

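HEK293 cells were transfected with 5 µg of empty vector, MAVS or STING plasmid and harvested after 24 hours, per the labels' protocols. Cells were treated with cycloheximide for 30 minutes, and lysates were separated on 10% to 50% sucrose gradients and collected by absorbance at 254 nm. The labels call the fractions free and polysome and do not define the free fraction further. Polyadenylated RNA was amplified by Smart-seq2 with 12 to 14 cycles after addition of 0.4 µl of diluted ERCC spike-in RNA, and sequenced as 150 bp read pairs on an Illumina HiSeq X instrument. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1 and the genome build hg19. Each of the 6 groups (3 plasmids in 2 fractions) had 2 libraries, numbered 1 and 2.

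The deposited values are FPKM, per the file headers, in 1 table of 11529 lines. The table also holds the authors' deposited polysome-to-free ratio of each plasmid and number, which equals the quotient of the 2 FPKM columns to within 3.42e-09. The FPKM values were found not to be plain. Every value had been raised to at least 1 and then multiplied by 1 number per group: 1 for vector free, 1.555 for MAVS free, 1.985 for STING free, 4.86 for vector polysome, 8.585 for MAVS polysome and 9.155 for STING polysome. Dividing by these numbers returned 6-digit values for all entries, to a tolerance of 1e-09. The origin of the multipliers is not stated, and the design, written before the data were examined, assumed plain FPKM. Counts were not analysed here, so depth and counting error are unknown. Spike-in RNA was not used here, so changes in the total amount of mRNA were not measured.

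After removal of 14 duplicate lines, 11515 genes remained. The multipliers were divided out, and libraries were scaled by median-of-ratios factors over the 4947 genes above the floor in all 12 libraries. Because scaling spreads the floor of 1, values below the highest scaled floor (1.42) were raised to it. Genes above the floor in at least 2 libraries were tested, which left out 1105 genes and kept 10410. Values of log2(scaled FPKM + 1) were fitted in limma 3.58.1 under R 4.3.3 with 6 group means and 6 residual degrees of freedom, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over all tested genes at 0.05. The 9 comparisons were STING or MAVS against vector and STING against MAVS in polysomes, STING or MAVS against vector in the free fraction, the corresponding 3 differences of the polysome-to-free ratio, and vector polysomes against vector free. Calls with a fold change of at least 2 on this scale were 31 higher and 60 lower for STING polysomes and 5 and 0 for MAVS polysomes.

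The comparisons, the tests, 22 gene lists, the rule for naming genes and the first group of other settings were chosen before the data were examined. Of the lists 20 had members among the tested genes. They were tested with camera at a preset correlation of 0.01 and adjusted over 180 tests, of which 31 passed, and again with an estimated correlation, where 7 of the 31 passed. Called members were also counted with the adjustment over the members of a list only. The text names the plasmid genes. It also names, among called genes whose libraries did not overlap and whose mean reached 5 scaled FPKM in at least 1 group, up to 10 with the largest and 10 with the smallest fold change, and up to 4 members per list by p. For comparisons with fewer than 5 such genes in a direction, the 5 with the smallest p are given and said not to pass. For a ratio, the differences between same-numbered polysome and free libraries were required not to overlap, so this naming rule did pair libraries by number. Not all named genes of the larger sets are printed. A result that the rule selects is not reported here. Symbols of 20 genes had been stored as dates, and these and 1 symbol shared by several genes were not named.

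The fit was tested on simulated data in 10 runs with 200 changed genes each. At a log2 change of 1 it recovered 24.4% of changed genes for STING polysomes, 37.2% for STING free and 11.9% for the ratio. At a change of 2 it recovered 69.7%, 78.4% and 49.1%. The changed genes were drawn only from genes with a mean, taken on the log scale, above 5 scaled FPKM in both vector fractions. Recovery of lower genes was not tested. False calls were 14.9%, 55.0% and 40.5% of all calls, and 7.01%, 37.1% and 6.25% of calls above the floor in all libraries compared. In 20 simulations with no changed gene, medians of 3.5, 2 and 3 genes were called in the 3 polysome comparisons, 69 and 68.5 in the free comparisons and 12, 12 and 11 for the ratios. The shared spread lies above that of polysome libraries and below that of free libraries.

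Other settings chosen at that time were FPKM as deposited, quantile normalization, a pseudocount of 0.1, no filter, only the groups compared, no trend, the replicate number as a block over all groups or within a treatment, leaving out each library, fry in place of camera, and scaling by spike-ins, which was not run. A further 5 settings were chosen after seeing the data: only the libraries of 1 fraction, 1 variance per fraction, the multipliers divided out with no further scaling, deposited values with a common floor, and only genes above the floor in all 12 libraries. The closing section gives their effect. For shared vector libraries, correlations were compared with 20 simulations of unchanged groups. Transcript length, GC content and predicted hydrophobic segments were taken from GENCODE transcripts matched by symbol, which gave a length for 91.9% of tested genes. Proteins were translated from the longest open reading frame, and a segment was a window of 19 residues with mean hydropathy of at least 1.6. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.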

Results

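HEK293 cells, a human embryonic kidney line, were transfected with empty vector, a MAVS plasmid or a STING plasmid, and polyadenylated mRNA from sucrose gradients was sequenced 24 hours later. MAVS is the mitochondrial adaptor of the RNA sensors RIG-I and MDA5. STING, whose gene is listed here under its older symbol TMEM173, is the endoplasmic reticulum (ER) adaptor of the DNA sensor cGAS. For each plasmid the labels give a fraction called free and a fraction called polysome, the mRNA bound by several ribosomes. The 6 groups held 2 libraries each, 12 in all. By the series title, the question was whether STING brings about a selective translation program through the ER stress kinase PERK, with MAVS as the other sensor pathway.

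Expression was given as FPKM, so the number of reads per library is unknown and no counting interval could be given. Of 11515 genes, 7327 to 8049 lay above the lowest printed value in the free libraries and 8543 to 8919 in the polysome libraries. Replicates lay closer together in polysomes than in the free fraction. The median standard deviation of a gene between replicates was 0.0784 on the log2 scale in vector polysomes, 0.0740 in MAVS polysomes and 0.0813 in STING polysomes. The corresponding values of the free fraction were 0.176, 0.201 and 0.174. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples. All fold changes are on the log2(scaled FPKM + 1) scale, which understates the change of genes with low values. They are relative to the typical gene, because the deposited values carry 1 multiplier per group. With the multipliers left in, the median of all genes lay 0.79 higher for STING against vector in polysomes and 0.82 higher for MAVS. It lay 0.58 and 0.41 higher in the free fraction, and 2.23 higher for vector polysomes against vector free.

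The genes carried by the plasmids were examined first as a check of the labels. TMEM173 had a level of 57230 ± 2240 scaled FPKM in STING polysomes (SD, n = 2), against 11.25 ± 1.29 in vector polysomes. In STING free libraries it had 203900 ± 152, against 182.1 ± 11.8 in vector free libraries. It took 12.2% and 11.2% of the summed FPKM of the STING free libraries and 5.04% and 5.56% of the STING polysome libraries. MAVS had 1461 ± 42.5 in MAVS polysomes and 2.73 ± 0.122 in vector polysomes, and 1492 ± 84.0 in MAVS free against 122.6 ± 5.88 in vector free. Each plasmid gene was thus highest in the libraries labelled with it. The transfected genes were also read outside their own groups. MAVS free libraries held 6133 ± 9.25 for TMEM173, which is 3.01% of the STING free level, and MAVS polysomes held 79.87 ± 8.67, which is 0.14% of the STING polysome level. Vector free libraries held 8.22% of the MAVS free level for MAVS, while STING free libraries held 0.44%.

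**Figure D1:**
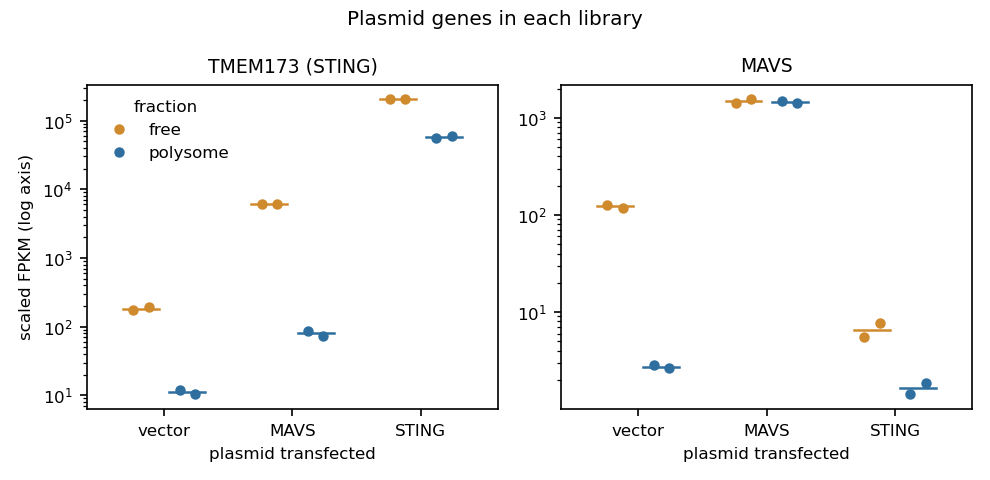
Scaled FPKM (log axis) of TMEM173, the gene of STING, and of MAVS in each library, by plasmid transfected (x axis) and fraction (colour); points are the 2 libraries of a group and bars their mean. TMEM173 was highest in STING libraries (203900 free, 57230 polysome) and lay at 6133 in MAVS free libraries and 182.1 in vector free libraries.

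The first comparison asked which mRNAs changed in polysomes when STING was expressed. ISG15, a ubiquitin-like interferon-stimulated gene, rose from 63.5 ± 0.612 scaled FPKM in vector polysomes to 447.7 ± 32.0 in STING polysomes (SD, n = 2; log2 fold change 2.80 ± 0.129 SE, adjusted p = 0.000278, limma). FOS, a stress-induced transcription factor, rose by 1.18 ± 0.104 (adjusted p = 0.00299), from the floor in both vector libraries. CSRNP1, a nuclear protein, rose by 2.13 ± 0.229 (adjusted p = 0.00625). EEF2, the translation elongation factor that moves the ribosome along the mRNA, rose from 87.82 ± 3.16 to 252.3 ± 32.6 (1.51 ± 0.128, adjusted p = 0.00268). TIMP1, a secreted inhibitor of matrix metalloproteinases, fell from 800.8 ± 71.9 to 296.6 ± 3.88 (-1.43 ± 0.0964, adjusted p = 0.00149). In all, 353 of 10410 genes passed the threshold for STING against vector in polysomes, 122 higher and 231 lower.

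Further genes rose in STING polysomes. ATF3, a stress-induced transcription factor, rose by 2.33 ± 0.382 (adjusted p = 0.0240). The proapoptotic genes PMAIP1 (NOXA) and BBC3 (PUMA) rose by 2.14 ± 0.251 and 1.72 ± 0.309. NFKBIA, which encodes the inhibitor of NF-kB, rose by 1.24 ± 0.180, and GADD45A, a DNA damage response gene, by 1.33 ± 0.252. The remaining genes with the largest rises were HES4 at 2.01, NASP at 1.54 and SH2D3C at 1.47. On the other side, TM7SF2, a sterol reductase of the ER membrane, fell by 1.71 ± 0.301, and INSIG1, the ER membrane protein that holds back SREBP, fell by 1.37 ± 0.184. TMEM234 and TMEM53, named as transmembrane proteins, had log2 fold changes of -1.66 and -1.65. PIGF, of glycolipid anchor synthesis, had -1.55 and TMBIM4 had -1.52. BCKDK, a mitochondrial kinase, had -1.46, B9D1, a ciliary protein, had -1.43, and WDR54 had -1.39; all of these passed the threshold.

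Target genes of the integrated stress response, driven by the transcription factors ATF4 and CHOP, were higher in STING polysomes as a group. Of 37 members tested 33 were higher and 2 lower, with a median log2 fold change of 0.82. Called as higher were 5 members over all genes and 15 adjusted over the list alone, with none called lower (camera adjusted p = 9.42e-12; adjusted p = 0.0268 with an estimated correlation). MTHFD2, of mitochondrial folate metabolism, rose by 1.30 ± 0.175, CHAC1, which degrades glutathione, by 1.12 ± 0.170, and CTH, of cysteine synthesis, by 1.07 ± 0.185. ATF4 itself, listed among 17 mRNAs with upstream open reading frames, rose by 0.41 (adjusted p = 0.0389). That list of upstream open reading frame mRNAs had 1 member called higher and SLC35A4 called lower at -0.71, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0572). ER chaperones, targets of the other 2 ER stress branches, did not pass as a list of 25 (adjusted p = 0.566). Called lower were 2 of them, also 2 adjusted over the list alone: SDF2L1 at -1.35 ± 0.149 and MANF at -0.86.

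All 17 of the other 5-prime TOP mRNAs, which share a pyrimidine tract at their start and are controlled by mTOR, had positive fold changes with a median of 0.66. Of them 8 were called higher over all genes and 16 adjusted over the list alone (camera adjusted p = 1.89e-19; adjusted p = 0.00714 with an estimated correlation). EEF1A1 rose by 0.74, GNB2L1 (RACK1) by 0.70 and EEF1G by 0.66. Among 77 cytosolic ribosomal protein genes the median was 0.24, and 13 were called higher over all genes and 26 adjusted over the list alone (camera adjusted p = 1.23e-12). That list was not past the threshold with an estimated correlation (adjusted p = 0.524 with an estimated correlation). RPL5 rose by 1.00 ± 0.0849, RPL3 by 0.63 ± 0.0651, RPS4X by 0.54 and RPL7 by 0.53. Ribosomal protein genes and EEF1A1 have many near-identical copies in the genome, so their levels are uncertain.

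Nuclear-encoded genes of oxidative phosphorylation were lower in STING polysomes, with a median of -0.32 over 74 genes. Called were 10 lower and 0 higher over all genes, and 23 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.20e-12; adjusted p = 0.427 with an estimated correlation). The complex I subunits NDUFS8 and NDUFB9 fell by 0.88 ± 0.102 and 0.76 ± 0.0798. With the group multipliers left in, this list was not past the threshold (camera adjusted p = 0.466). Its median was then -0.31 relative to genes above the highest floor in all libraries compared. The oxidative phosphorylation list was also lower with MAVS against the same vector polysome libraries (median -0.26). Between STING and MAVS in polysomes it did not pass (median -0.09, camera adjusted p = 0.141), so a fall particular to STING was not shown. Immediate early genes had a median of 0.98 over 11 members, with 2 called higher (FOS and ATF3) and 7 adjusted over the list alone (camera adjusted p = 1.62e-05; adjusted p = 0.0830 with an estimated correlation). Cell cycle genes had a median of 0.30 over 29 members, none of them called over all genes or adjusted over the list alone (camera adjusted p = 0.00186; adjusted p = 0.132 with an estimated correlation). Cholesterol synthesis genes had a median of -0.11 over 19 members, with INSIG1 called lower over all genes and 5 lower adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.177 with an estimated correlation).

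The other lists did not pass the threshold in STING polysomes. Interferon genes, 28 in all, had a median of 0.01 (adjusted p = 0.316), with ISG15 called higher and IFI6, also interferon-stimulated, called lower at -1.25. These 2 were also the members called when adjusted over the list alone. Adjusted p was 0.157 for 20 NF-kB targets with NFKBIA called, 0.236 for 18 p53 targets with BBC3 and GADD45A called, and 0.553 for 16 cell death regulators with PMAIP1, BBC3 and MCL1 called. Called higher when adjusted over the list alone were 1, 2 and 4 members of these lists, and 1 cell death regulator was called lower. Initiation factors and eIF2alpha kinases had 0.0764 with EIF3D and EIF1 called higher, and also 2 adjusted over the list alone. DNA repair genes had 0.0764 with MSH6 called higher, also 1 adjusted over the list alone. Heat shock genes had 0.313 with HSPB1 and HSPE1 called lower, and 1 higher and 2 lower adjusted over the list alone. Matrix genes had 0.780 with TIMP1 called lower, and 1 higher and 1 lower adjusted over the list alone. Lysosome genes had 0.808 with CTSB called lower, and 1 higher and 2 lower adjusted over the list alone. Nucleic acid sensing genes (0.765) and blood and liver markers (0.653) had 0 members called, also when adjusted over the list alone.

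The count of called genes for STING against vector in polysomes depended on the model of the spread and on the scaling. It was 769 when only polysome libraries entered the fit and 82 when only the 4 libraries compared did. Of the 353 calls, 262 were among the 769, and 41 of the 49 named genes called here were called there too. The 8 that were not were HES4 (adjusted p = 0.0886), HSPE1 (0.0849), MCL1, CTSB, ATF4, ATP5G1, CTH and RPS4X (0.0508 for the last 2). Without vector library 1 or 2, or STING library 1 or 2, 121 (45 higher, 76 lower), 165 (43, 122), 157 (101, 56) and 185 (107, 78) genes were called, so lower calls no longer prevailed without either STING library. In these fits 20, 24, 19 and 20 of the 49 named genes kept their call. The 17 that kept it without each of these libraries in turn were TMEM173, ISG15, FOS, CSRNP1, EEF2, EEF1A1, EEF1G, GNB2L1, RPL3, RPL5, RPL7, RPS4X, TIMP1, SDF2L1, B9D1, NDUFB9 and NDUFS8. The split of higher to lower calls was 123 to 150 with quantile normalization, 82 to 445 with the group multipliers divided out and no further scaling, 5679 to 31 with the multipliers left in and 5179 to 59 with these and a common floor. Among genes above the floor in all 12 libraries it was 99 to 329.

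**Figure D2:**
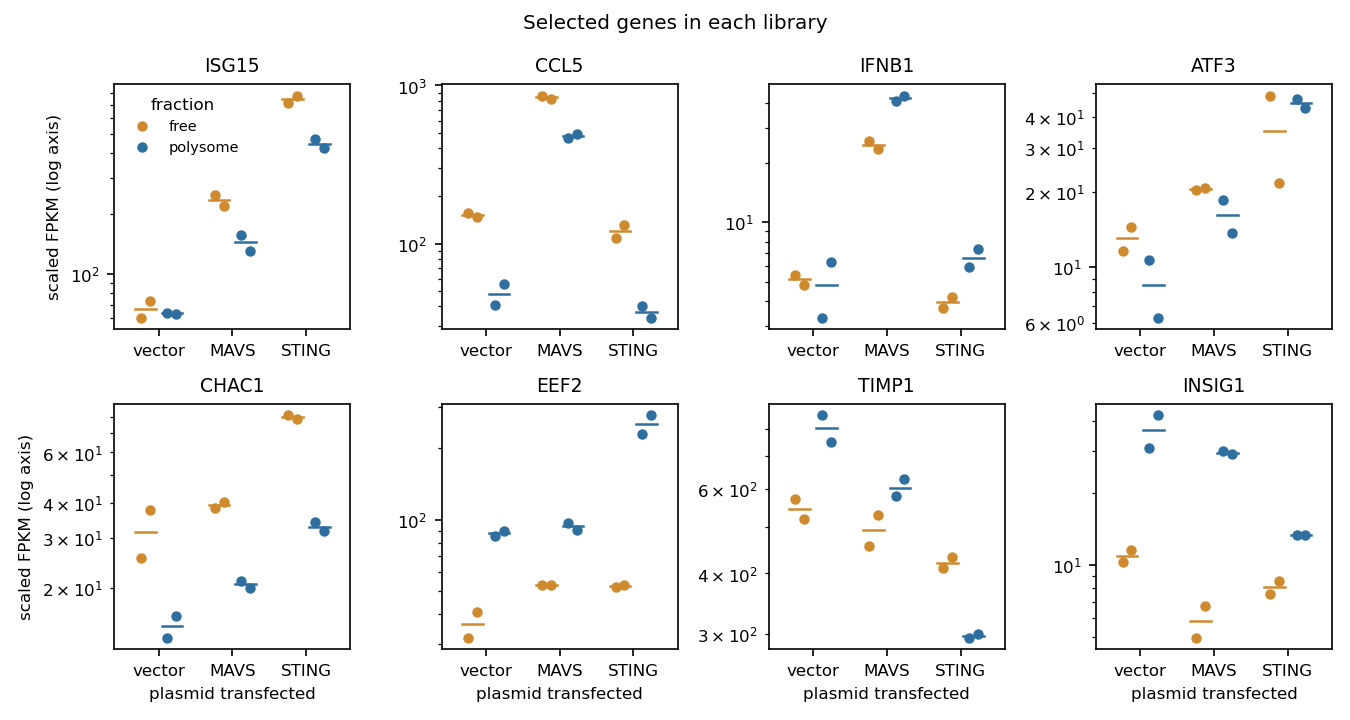
Scaled FPKM (log axes that do not start at 0) of 8 genes in each library, by plasmid transfected (x axis) and fraction (colour); points are the 2 libraries of a group and bars their mean. In polysomes ISG15 was 63.5 with vector, 144.0 with MAVS and 447.7 with STING, CCL5 was highest with MAVS (481.3), and TIMP1 was lowest with STING (296.6).

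With MAVS fewer genes passed in polysomes, and 3 of the 12 called were on the interferon list. CCL5, a chemokine, rose from 48.16 ± 10.3 scaled FPKM in vector polysomes to 481.3 ± 19.3 in MAVS polysomes (SD, n = 2; log2 fold change 3.31 ± 0.155 SE, adjusted p = 0.000342, limma). IFNB1, interferon beta, rose from 4.812 ± 2.15 to 42.16 ± 1.88 (2.94 ± 0.250, adjusted p = 0.0106), and ISG15 rose from 63.5 ± 0.612 to 144.0 ± 18.7 (1.16 ± 0.129, adjusted p = 0.0396). Of 28 interferon genes 18 were higher and 2 lower, with a median of 0.20. Called higher were 3 over all genes and 8 adjusted over the list alone, with none lower (camera adjusted p = 2.42e-12; adjusted p = 0.0269 with an estimated correlation). IFIT1, at 7.306 ± 0.442 in MAVS polysomes and at the floor in vector polysomes, had a log2 fold change of 1.78 that did not pass (adjusted p = 0.0741).

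Few genes were called lower in MAVS polysomes. ATP5B, the beta subunit of ATP synthase, fell by 0.36 ± 0.0404 (adjusted p = 0.0398), a call lost in the fit of polysome libraries alone (adjusted p = 0.161), under quantile normalization (1) and without each of the 4 libraries in turn (0.0557 to 0.120). The genes next in rank did not pass the threshold. These were MRPL48 at -0.54 (adjusted p = 0.0753), TTYH2 at -0.18, RAMP1 at -0.45, PRDX5 at -0.51 and PPIB at -0.40 (adjusted p = 0.141). The 74 oxidative phosphorylation genes had a median of -0.26, with ATP5B called lower and 3 lower adjusted over the list alone (camera adjusted p = 1.19e-20; adjusted p = 0.329 with an estimated correlation). The 77 ribosomal protein genes had a median of -0.20 with none called over all genes or adjusted over the list alone (camera adjusted p = 5.57e-21; adjusted p = 0.454 with an estimated correlation). The ribosomal direction did not hold under quantile normalization, where the median was 0.02 (adjusted p = 0.403). The stress response targets had a median of 0.06 with 0 called, also when adjusted over the list alone (camera adjusted p = 0.0764).

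In all, 12 of 10410 genes passed for MAVS against vector in polysomes, 10 higher and 2 lower, and 491 had an unadjusted p under 0.05. Within polysome libraries alone 11 passed, among them MAVS, TMEM173 and CCL5, while IFNB1 and ISG15 each had an adjusted p of 0.156. Without vector library 1 or 2, or MAVS library 1 or 2, 20 (6 higher, 14 lower), 20 (7, 13), 45 (43, 2) and 40 (38, 2) genes passed; MAVS, TMEM173, CCL5 and IFNB1 passed each time. Higher to lower calls were split 5 to 0 with quantile normalization, 10 to 0 with the multipliers divided out and no further scaling, 6064 to 2 with them left in and 5960 to 7 with these and a common floor.

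STING and MAVS were then compared directly in polysomes. CCL5 was lower with STING by a log2 fold change of -3.67 ± 0.155 (adjusted p = 0.000164, limma), at 36.91 ± 4.5 scaled FPKM against 481.3 ± 19.3 (SD, n = 2). IFNB1 had -2.50 ± 0.250 (adjusted p = 0.00488), ISG20, an interferon-induced exonuclease, had -2.48 ± 0.466, IFI6 had -1.55 ± 0.235 and IL29, interferon lambda 1, had -1.29 ± 0.159. ISG15 went the other way and was higher with STING, at 447.7 ± 32.0 against 144.0 ± 18.7 (1.63 ± 0.129, adjusted p = 0.00283). The interferon list thus had 6 members called lower and 1 higher, the same numbers as adjusted over the list alone (camera adjusted p = 0.00503; adjusted p = 0.292 with an estimated correlation).

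Stress response targets were higher with STING than with MAVS, with a median of 0.64, 3 of 37 called higher over all genes and 9 adjusted over the list alone (camera adjusted p = 8.71e-10; adjusted p = 0.0269 with an estimated correlation). The called members were SHMT2 and MTHFD2, both of mitochondrial one-carbon metabolism, at 1.18 ± 0.208 and 1.06 ± 0.175, and the amino acid transporter subunit SLC3A2 at 0.88 ± 0.171. The 17 other 5-prime TOP mRNAs had a median of 0.56, with 6 called higher and 16 adjusted over the list alone (camera adjusted p = 5.41e-17; adjusted p = 0.00714 with an estimated correlation). EEF2 was higher by 1.41 ± 0.128, GNB2L1 by 0.86 ± 0.0582 and BTF3 by 0.56 ± 0.0595. Ribosomal protein genes were higher in 76 of 77 cases, with a median of 0.43, 23 called higher and 51 adjusted over the list alone (camera adjusted p = 1.47e-36; adjusted p = 0.329 with an estimated correlation). Immediate early genes had a median of 0.51 with FOS called higher and 2 adjusted over the list alone (camera adjusted p = 0.000986; adjusted p = 0.177 with an estimated correlation). Cell cycle genes had a median of 0.31 with none called over all genes or adjusted over the list alone (camera adjusted p = 0.000157; adjusted p = 0.0746 with an estimated correlation).

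Among single genes, CSRNP1 was higher with STING than with MAVS by 1.78, GATA2 by 1.48, SH2D3C by 1.40, FAM89A by 1.25, RPL13A by 1.23 and TES by 1.21. TIMP1 was lower with STING at -1.02 ± 0.0964, INSIG1 at -1.09 ± 0.184, TM7SF2 at -1.54 and SDF2L1 at -1.11. WRB, an ER receptor for tail-anchored proteins, had -1.44, TMBIM4 had -1.40 and DUSP23 had -1.35. In all, 293 of 10410 genes passed for STING against MAVS in polysomes, 122 higher and 171 lower, and 617 passed in the fit of polysome libraries alone. Named genes that did not pass there were GATA2 (adjusted p = 0.0823), RPL15, SHMT2, MANF, SH2D3C, TMBIM4, MTHFD2 and IL29 (0.0528). Without MAVS library 1 or 2, or STING library 1 or 2, 102 (34 higher, 68 lower), 107 (43, 64), 145 (102, 43) and 160 (99, 61) passed. Of the 39 named genes called 17, 17, 20 and 20 kept their call, and 15 did so each time, among them CCL5, IFNB1, ISG15, FOS, EEF2, GNB2L1 and TIMP1. Other scalings gave a split of higher to lower of 78 to 413 with the multipliers divided out and no further scaling and 140 to 326 with them left in.

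**Figure D3:**
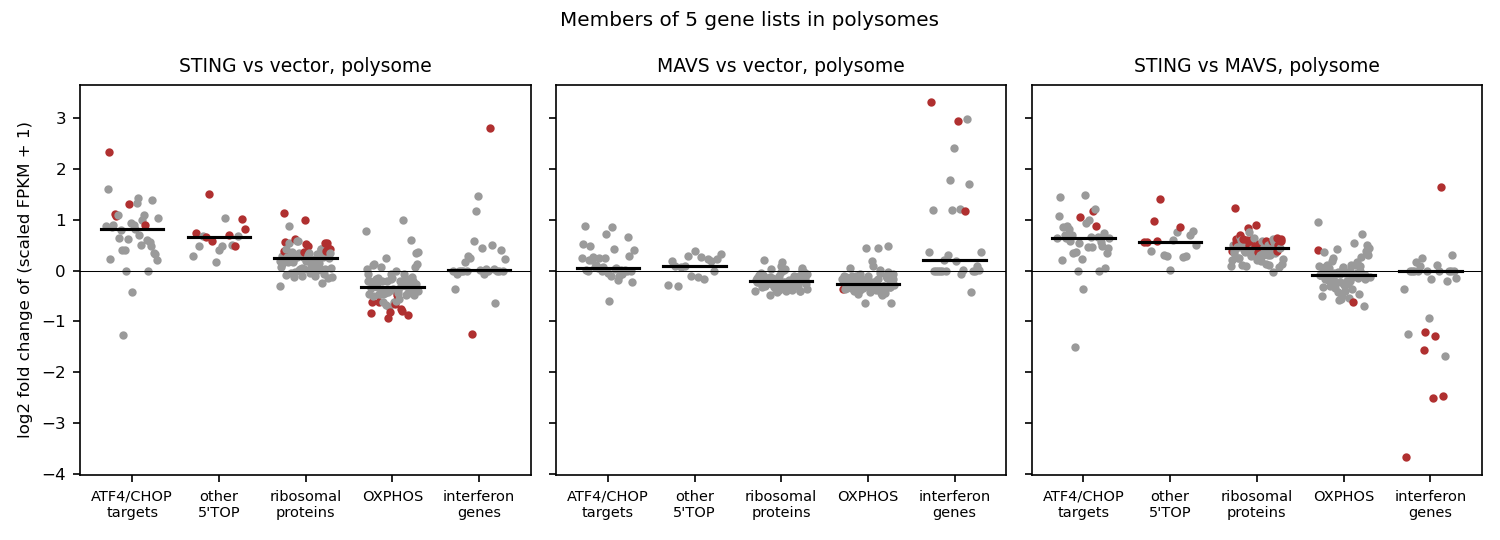
Log2 fold change of (scaled FPKM + 1) in polysomes (y axis) for the members of 5 gene lists (x axis) in 3 comparisons (panels); each point is a gene, red points passed an adjusted p of 0.05 over all genes, and black bars are medians. Medians of the ATF4 and CHOP targets were 0.82 for STING against vector, 0.06 for MAVS against vector and 0.64 for STING against MAVS; the median of the ribosomal protein genes in MAVS polysomes was not lower under quantile normalization (0.02).

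The fold changes of STING and MAVS in polysomes share their vector libraries. Across 10410 genes, which are not independent replicates, Pearson r was 0.357, below the mean of 0.499 (0.473 to 0.521) of 20 simulations with unchanged groups. The covariance was 0.0385 against 0.0174 simulated. ISG15 and TMEM173 were called higher in both comparisons and 1 gene lower in both, where simulations with unchanged groups shared a median of 0 (up to 2) and 1 (up to 4) and independent lists would share 0.117 and 0.0444. In the free fraction r was 0.459 against 0.5 (0.466 to 0.519) simulated, the covariance was 0.111 against 0.0718, and 27 genes were higher in both and 50 lower in both. Simulations with unchanged groups shared medians of 6 (up to 10) and 18 (up to 29), and independent lists would share 2.54 and 2.77. For the polysome-to-free ratio r was 0.440 against 0.497 (0.461 to 0.511), the covariance was 0.117 against 0.0885, and 10 genes were higher and 2 lower in both, against 4 (up to 9) and 1 (up to 3) simulated and 0.0648 and 0.0849 for independent lists. With 2 vector libraries per fraction, separate controls of 2 libraries each could not be formed. The simulations also shared their vector libraries, so part of the excess over independent lists may come from the shared controls. Whether shared controls add to the excess over the simulations was not tested.

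In the free fraction ISG15 rose with STING from 66.84 ± 9.50 to 745.9 ± 45.8 scaled FPKM (SD, n = 2; log2 fold change 3.47 ± 0.129 SE, adjusted p = 4.08e-05, limma). PCNA, the sliding clamp of DNA replication, rose from 45.17 ± 0.769 to 117.0 ± 7.77 (1.35 ± 0.122, adjusted p = 0.00219). NFKBIA rose by 2.22 ± 0.180, PMAIP1 by 2.08 ± 0.251, the cytokine gene TNF by 2.05 ± 0.273, FOS by 1.72 ± 0.104 and DNAJA2, a cochaperone, by 2.31 ± 0.211. MT2A, a metallothionein, fell by 1.89 ± 0.306, and HSPA5, the ER chaperone BiP, fell by 1.05 ± 0.155. The MAVS signal was lower with STING at -4.05 ± 0.141 (adjusted p = 3.14e-05), which rests on the level of 122.6 read in vector free libraries, where no MAVS plasmid was given. Of these, ISG15, PCNA and MAVS, as well as TMEM173, also passed in the fit of free libraries alone. The others named here did not, among them NFKBIA (adjusted p = 0.0688), FOS (0.0695) and PMAIP1 (0.138).

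Stress response targets were also higher in the free fraction with STING, with a median of 0.62, 4 of 37 called higher and 11 adjusted over the list alone (camera adjusted p = 6.45e-07; adjusted p = 0.0498 with an estimated correlation). CTH rose by 1.92 ± 0.185, CHAC1 by 1.34 ± 0.170, PPP1R15A by 1.47 ± 0.329 and VEGFA by 0.77 ± 0.143. None of these 4 passed among free libraries alone (adjusted p = 0.0712, 0.146, 0.337 and 0.247). The 17 other 5-prime TOP mRNAs had a median of 0.21, with 4 called higher and 5 adjusted over the list alone (camera adjusted p = 8.97e-05; adjusted p = 0.0618 with an estimated correlation). The 74 oxidative phosphorylation genes had a median of -0.20, with 6 called lower and 1 higher, and 10 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.000558; adjusted p = 0.683 with an estimated correlation). Under quantile normalization that list was at -0.04 (adjusted p = 0.551). Immediate early genes had a median of 0.83 with FOS called higher and 4 adjusted over the list alone (camera adjusted p = 0.00415; adjusted p = 0.246 with an estimated correlation).

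The free fraction held 582 called genes for STING against vector, 247 higher and 335 lower, but only 20 passed in the fit of free libraries alone, of which 17 were among the 582. Simulations in which no gene changed gave a median of 69 and up to 100 calls in this comparison. The median of simulated calls above the floor in all libraries compared was 24.5. The shared estimate of the spread lies below that of free libraries, but many of the simulated calls also involved a floor value. Of the 582 calls, 123 had a floor value. Calls were split, higher to lower, 101 to 1051 with the multipliers divided out and no further scaling, 3013 to 78 with them left in and 888 to 24 with these and a common floor. Other genes with large fold changes were CYR61 at 2.83, SERPINF1 at 2.36, SDCBP at 2.32 and PPAPDC1B at -2.97, none of which passed among free libraries alone (adjusted p = 0.155 to 0.269). Without vector library 1 or 2, or STING library 1 or 2, the split was 265 to 512, 227 to 464, 494 to 314 and 417 to 344. Of the 61 named genes called here 43, 34, 40 and 42 kept their call, and 31 did so each time, among them ISG15, PCNA, NFKBIA, FOS, PMAIP1, TNF, CTH and CHAC1.

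MAVS raised CCL5 in the free fraction from 151.8 ± 5.74 to 844.1 ± 26.3 scaled FPKM (SD, n = 2; log2 fold change 2.47 ± 0.155 SE, adjusted p = 0.000862, limma). IFNB1 rose from 5.158 ± 0.425 to 24.56 ± 1.73 (2.05 ± 0.250, adjusted p = 0.0128), ISG15 rose by 1.79 ± 0.129 (adjusted p = 0.00110) and NFKBIA by 1.04 ± 0.180 (adjusted p = 0.0402). The interferon list had a median of 0.00 with these first 3 genes called higher, also 3 adjusted over the list alone (camera adjusted p = 0.0501). Stress response targets had a median of 0.25 with 0 called, also when adjusted over the list alone (camera adjusted p = 0.0378; adjusted p = 0.329 with an estimated correlation). Other 5-prime TOP mRNAs had a median of 0.17, with GNB2L1 called higher and 2 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.177 with an estimated correlation). Ribosomal protein genes had a median of 0.10, with 2 called higher and 3 adjusted over the list alone (camera adjusted p = 0.000725; adjusted p = 0.756 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.12, with ATP5B and NDUFB5 called lower and 2 adjusted over the list alone (camera adjusted p = 0.000785; adjusted p = 0.683 with an estimated correlation). Under quantile normalization the ribosomal and oxidative phosphorylation lists had adjusted p of 0.308 and 0.117.

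In all, 193 genes passed for MAVS against vector in the free fraction, 107 higher and 86 lower, and 11 passed in the fit of free libraries alone, with TMEM173, MAVS and CCL5 among them. IFNB1, ISG15 and NFKBIA had adjusted p of 0.148, 0.0889 and 0.391 there. Simulations without any change gave a median of 68.5 and up to 91 calls, and a median of 22 above the floor in all libraries compared. Of the 193 calls, 76 had a floor value. Without vector library 1 or 2, or MAVS library 1 or 2, 479 (168 higher, 311 lower), 395 (130, 265), 878 (647, 231) and 531 (390, 141) genes passed. Of the 29 named genes called, 18, 17, 28 and 17 kept their call, with CCL5, IFNB1, ISG15, FANCG and FBXO44 among the 12 that did so each time. FANCG, of the Fanconi anemia pathway, rose by 1.87, and FBXO44 was lower at -1.82; in free libraries alone each had an adjusted p of 0.284. Under other scalings the split of higher to lower was 41 to 98 with the multipliers divided out and no further scaling, 1387 to 24 with them left in and 410 to 5 with these and a common floor.

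The change of the polysome-to-free ratio was tested as the interaction of plasmid and fraction. Free and polysome libraries of the same number were treated as independent, because the labels do not say that they were paired. With the replicate number as a block within a treatment, almost no gene passed for the ratios, as the closing section gives. With STING the ratio fell for RAMP1, a receptor activity-modifying membrane protein, by 1.39 ± 0.0993 (adjusted p = 0.00322, limma). RAMP1 went from 214.8 ± 13.9 to 105.2 ± 2.06 scaled FPKM in polysomes and from 81.85 ± 2 to 106.0 ± 8.25 in the free fraction (SD, n = 2). The ratio fell by 2.33 ± 0.173 for NDUFAF1, an assembly factor of complex I near the floor in all groups but STING free (9.287 ± 1.25, adjusted p = 0.00366), by 1.06 ± 0.136 for TIMP1, by 1.22 ± 0.191 for MANF and by 1.35 ± 0.159 for the membrane enzyme MGST3. It rose for the ribosomal protein gene RPL3 by 0.88 ± 0.0921, for EEF1G by 0.53 ± 0.0730 and for CALR, the ER chaperone calreticulin, by 1.03 ± 0.158. Other 5-prime TOP mRNAs had a median of 0.40 for the ratio, with EEF1G called higher over all genes and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.27e-05; adjusted p = 0.0502 with an estimated correlation). Ribosomal protein genes had a median of 0.22, with RPL3 called higher and 2 adjusted over the list alone (camera adjusted p = 8.67e-07; adjusted p = 0.683 with an estimated correlation). Under quantile normalization their median was 0.02 (adjusted p = 0.339). Stress response targets did not pass for the ratio, with a median of 0.10 and 0 called, also when adjusted over the list alone (adjusted p = 0.685).

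In all, 97 genes passed for the ratio with STING against vector, 45 higher and 52 lower, and 57 of them lay above the floor in all 8 libraries compared. Without vector free library 1 or 2, STING free library 1 or 2, or vector polysome library 1 or 2, 364 (256 higher, 108 lower), 289 (207, 82), 405 (98, 307), 250 (56, 194), 31 (16, 15) and 27 (11, 16) genes passed. Without STING polysome library 1 or 2 the split was 65 to 18 and 59 to 23. Of the named genes 5 and 6 of 27 kept their call without vector polysome library 1 or 2 and 8 and 6 without STING polysome library 1 or 2. Of the 27 named genes called, TMEM173, MAVS, NDUFAF1, RAMP1 and CRB3, which lay near the floor in all but the vector free libraries, passed without each library in turn. With other scalings, higher to lower calls were 9 to 4 with the multipliers divided out and no further scaling, also 9 to 4 with them left in, and 2368 to 116 with these and a common floor. Among genes above the floor in all 12 libraries they were 8 to 44.

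With MAVS, 32 genes passed for the ratio, 15 higher and 17 lower, of which 8 lay above the floor in all libraries compared. MDK, a secreted growth factor, had a ratio higher by 0.83 ± 0.0890 (adjusted p = 0.0157), with 1008 ± 53.4 and 1000 ± 21.6 scaled FPKM in vector and MAVS polysomes and 1929 ± 71.4 and 1074 ± 37.4 in the free fraction (SD, n = 2). FTL, the light chain of ferritin, had a ratio lower at -0.65 ± 0.0849 (adjusted p = 0.0391), LITAF had 1.73, NT5DC2 had -0.75 and C9orf103 had -1.24. Ribosomal protein genes had a lower ratio in 75 of 77 cases with a median of -0.29, 0 called over all genes and 1 lower adjusted over the list alone (camera adjusted p = 2.02e-15; adjusted p = 0.510 with an estimated correlation). That direction was lost under quantile normalization, with a median of 0.00 (adjusted p = 0.727). Interferon genes had a median of 0.22 with 0 called over all genes and 1 higher adjusted over the list alone (camera adjusted p = 0.0280; adjusted p = 0.355 with an estimated correlation). Without vector free library 1 or 2, MAVS free library 1 or 2, vector polysome library 2 or MAVS polysome library 2, 292 (219 higher, 73 lower), 228 (169, 59), 555 (116, 439), 308 (59, 249), 18 (5, 13) and 51 (35, 16) genes passed. Without vector polysome library 1 or MAVS polysome library 1 the split was 10 to 19 and 34 to 12. Of the named genes, 4 and 3 of 11 kept their call without vector polysome library 1 or 2 and 5 and 6 without MAVS polysome library 1 or 2. TMEM173 and MAVS alone passed without each library in turn. Higher against lower calls numbered 1 to 2 with quantile normalization, 43 to 1 with the multipliers left in and 2511 to 15 with these and a common floor.

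Between STING and MAVS the ratio was higher for RPL3 by 0.94 ± 0.0921 (adjusted p = 0.0104, limma), for EEF2 by 1.43 ± 0.181 and for MSH6, a mismatch repair protein, by 1.07 ± 0.162. It was lower for IL29 at -2.53 ± 0.225 (adjusted p = 0.00788), for FKBP7, an ER folding enzyme, at -2.39 ± 0.267, for NDUFAF1 at -1.64 ± 0.173 and for B2M, the light chain of MHC class I, at -1.57 ± 0.230. IL29 lay at 5.130 ± 1.17 scaled FPKM in MAVS polysomes and at the floor in MAVS free, and at 1.484 ± 0.0888 in STING polysomes and 4.759 ± 0.931 in STING free (SD, n = 2). All 77 ribosomal protein genes had a higher ratio with STING than with MAVS, by a median of 0.51, with 2 called and 55 adjusted over the list alone (camera adjusted p = 5.95e-29; adjusted p = 0.397 with an estimated correlation). Under quantile normalization the median was 0.04 above that of all genes (adjusted p = 0.188). Other 5-prime TOP mRNAs had a median of 0.39, with EEF2 and EEF1G called higher and 8 adjusted over the list alone (camera adjusted p = 6.45e-07; adjusted p = 0.0327 with an estimated correlation). In all, 90 genes passed, 47 higher and 43 lower. Without MAVS free library 1 or 2, STING free library 1 or 2, or MAVS polysome library 1, 724 (528 higher, 196 lower), 440 (321, 119), 430 (120, 310), 304 (91, 213) and 51 (19, 32) genes passed. Without MAVS polysome library 2 the split was 30 to 40, and without STING polysome library 1 or 2 it was 65 to 21 and 65 to 24. Of the 27 named genes 5 and 6 kept their call without MAVS polysome library 1 or 2 and 12 and 12 without STING polysome library 1 or 2, with TMEM173, RPL3, IL29, FKBP7 and NDUFAF1 among them without each library in turn. By other scalings the split of higher to lower was 11 to 21 with quantile normalization, 10 to 6 with the multipliers divided out and no further scaling, 11 to 75 with them left in and 344 to 532 with these and a common floor. Among genes above the floor in all 12 libraries it was 15 to 39.

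Polysome and free fractions of vector cells were compared as a check on the fractionation. PRDX4, a peroxiredoxin of the ER, was higher in polysomes at 1290 ± 42.1 against 233.9 ± 68.7 scaled FPKM (SD, n = 2; log2 fold change 2.49 ± 0.223 SE, adjusted p = 0.000535, limma). ANAPC5, a subunit of the anaphase-promoting complex, was higher by 3.05 ± 0.495, CRELD2, of the ER stress response, by 2.79 ± 0.537 and DHRS13 by 2.58 ± 0.317. SEPW1, a selenoprotein, was lower in polysomes at 268.9 ± 0.191 against 2884 ± 123 (-3.42 ± 0.115, adjusted p = 1.19e-05). PPDPF had -3.58 ± 0.184, the small heat shock protein gene HSPB1 -2.23 ± 0.0992, and the proapoptotic gene BAX -2 ± 0.186. ATF4, whose upstream open reading frames hold back its translation in unstressed cells, was lower in polysomes at 349.1 ± 29.8 against 1279 ± 7.71 (-1.87, adjusted p = 3.05e-05).

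Ribosomal protein genes were lower in vector polysomes than in the free fraction, with a median of -0.45 over 77 genes, 39 called lower and 3 higher, and 42 lower and 8 higher adjusted over the list alone (camera adjusted p = 5.25e-09; adjusted p = 0.640 with an estimated correlation). RPL12 had -1.95 ± 0.105, RPSA -1.56 ± 0.102 and RPL23A -1.55 ± 0.0861, while RPL3 had 0.91 ± 0.0651. The direction of the list turned under quantile normalization, with a median of 0.23 (adjusted p = 0.0493). Oxidative phosphorylation genes, at a median of -0.20 with 25 called lower and 10 higher, did not pass (adjusted p = 0.0764), and 28 lower and 15 higher were called when adjusted over the list alone. Among lysosome genes the proteases CTSL1, CTSB and CTSD were higher in polysomes by 2.22 ± 0.272, 1.16 ± 0.142 and 0.74 ± 0.0797, while the list did not pass (adjusted p = 0.0916), with 7 members higher adjusted over the list alone. In all, 1711 genes passed, 816 higher and 895 lower. Without vector polysome library 1 or 2, 1089 and 905 genes passed, and 57 and 50 of the 77 named genes kept their call; without vector free library 1 or 2, 61 and 64 did. Scaled in other ways, the split of higher to lower was 2324 to 618 with the multipliers divided out and no further scaling, 10025 to 14 with them left in and 5870 to 7 with these and a common floor.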

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

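The tests of index hopping, of the STING plasmid in the MAVS plasmid, of a lower mRNA level in both fractions and of the share of reads were chosen only after the result was seen, and the set of TMEM-named genes was chosen after seeing the called genes and after looking at other sets of gene families.

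Genes whose change differed between the polysome and the free fraction, by the interaction test, are given first (log2, adjusted p). With STING the interaction was 2.07 for TMEM173 (0.00222; 12.19 in polysomes and 10.12 in free), 3.54 for MAVS (0.00114; -0.51 and -4.05) and -1.06 for TIMP1 (0.0265; -1.43 and -0.37). It was -2.43 for SERPINF1 (0.0475; -0.07 and 2.36) and 1.99 for CRB3 (0.0183; -0.26 and -2.25). With MAVS it was -2.34 for TMEM173 (0.000935; 2.72 and 5.07), 5.02 for MAVS (0.000158; 8.62 and 3.59), 1.99 for CRB3 (0.0159; -0.26 and -2.25) and 1.69 for PPP1R1C (0.0322; 0.19 and -1.50). CRB3 and PPP1R1C lay near the floor in all groups but vector free (10.56 ± 0.642 and 6.433 ± 1.01 scaled FPKM, SD, n = 2), so their values rest mainly on the 2 vector free libraries. The interactions of the MAVS gene, with STING and with MAVS, rest on its level of 122.6 in vector free libraries, against 2.73 in vector polysomes. With the MAVS plasmid its level was alike in both fractions, at 1461 in polysomes and 1492 in free.

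The TMEM173 signal in MAVS free libraries was 33.7 times that in vector free libraries, which argues against reads of the STING libraries spread evenly over all others. The polysome-to-free ratio of TMEM173 differed between STING and MAVS by 4.42 ± 0.137 SE (log2), which argues against STING plasmid among the MAVS plasmid if a plasmid transcript associates with polysomes alike in both groups. Material of STING free libraries in the MAVS free libraries, at a share of 3.01%, cannot be told apart: 0 genes other than TMEM173 lay below that share of their STING free level, and no other gene was low enough to decide it. A rise of the endogenous gene with MAVS, which the design allows, was not tested and stays open.

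The median of TMEM-named mRNAs in STING polysomes, compared with genes without a predicted segment, stayed at -0.509 ± 0.0764 after length, GC content and level were removed, which argues against transcript length and GC content as the whole cause. For the polysome-to-free ratio the difference, with nothing removed, was -0.413 ± 0.0762. The set was chosen after seeing the genes called in these polysome libraries, whose values also enter the ratio. The ratio therefore cannot decide on an equally lower mRNA level in both fractions. TMEM173 took a larger share of the summed FPKM in STING free than in STING polysomes. The difference in STING free was -0.0963 ± 0.0631 against -0.494 ± 0.111 in polysomes, with nothing removed. This comparison cannot decide on the share of reads taken by the plasmid transcript. Such a share lowers all other genes of a library by 1 factor. Apart from the floor and the pseudocount, that factor cancels from the difference between TMEM-named mRNAs and the other genes. An effect of STING, an ER protein, on these mRNAs stays open and untested, since the pattern was found and tested in the same data, and the SEs are over genes and not over cultures.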

How the results depend on the processing

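The fits within 1 fraction, with 1 variance per fraction, with the multipliers divided out, with a common floor and of genes above the floor in all libraries were chosen only after the result was seen. Of 326 named calls 322 kept their sign under every alternative run for named genes, which left out the common floor. With FPKM as deposited, their fold changes were taken relative to the median of genes above the highest floor in all libraries compared. Of the counts outside the leave-out fits 46 stayed within 1.5 times and 62 did not; a pseudocount of 0.1 and no filter moved none beyond that. Scaling by spike-ins was not run. Where no construction is given, the cause was not tested. With 2 libraries per group and unknown depth, small changes of low genes were beyond reach. Counts below are in the order STING, MAVS and STING against MAVS in polysomes, STING and MAVS in free, the ratio for STING, MAVS and STING against MAVS, and vector polysome against free, where 353, 12, 293, 582, 193, 97, 32, 90 and 1711 genes were called.

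FPKM as deposited gave 5710, 6066, 466, 3091 and 1411 in the first 5, 13 for the STING ratio and 10039 for vector. The multipliers move most genes together in the comparisons with vector within a fraction and in vector polysomes against free. The counts of 466 and 13 lay near those with the multipliers divided out (491 and 13), so the multipliers alone do not account for these. The common floor gave 5238, 5967, 1991, 912, 415, 2484, 2526, 876 and 5877, and a polysome correlation of 0.498 against 0.357. The multipliers divided out gave 491 for STING against MAVS in polysomes, 1152 for STING free, 13, 4 and 16 for the ratios and 2942 for vector. Quantile normalization gave 5 for MAVS polysomes, 66 for MAVS free and 40, 3 and 32 for the ratios.

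Only the groups compared, with fewer degrees of freedom, gave 82, 1, 135, 1 and 1 in the first 5, 9 and 43 for the MAVS and STING against MAVS ratios and 731 for vector. Only the libraries of the fraction gave 769, 617, 20 and 11 for STING polysomes, STING against MAVS polysomes, STING free and MAVS free. With 1 variance per fraction the counts were 1633, 131, 1552, 74 and 53 in the first 5 and 45 and 49 for the STING and STING against MAVS ratios; this fit gave 25.5% false calls for STING polysomes in simulated data. No trend gave 5 for MAVS polysomes and 57 for the STING against MAVS ratio. Only genes above the floor in all libraries gave 6 for MAVS polysomes, 83 for MAVS free and 52, 2 and 54 for the ratios, with fewer genes tested.

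The replicate block over all groups gave 6 for MAVS polysomes, 105 for MAVS free and 25, 20 and 50 for the ratios. The replicate block within a treatment gave 0, 1 and 0 for the ratios (1004 and 1173 at an unadjusted p under 0.05 for the first and last) and 1001 for vector. Pairing was not taken from the numbers in the main fit, though the rule for naming genes of a ratio used same-numbered differences. Deviations of same-numbered libraries correlated at -0.0627 to 0.133 over 15 pairs of groups, 1 of them over 0.1. Of 12 libraries, 6 were closest to their own number. Leaving out 1 library, with the lone library assumed to vary like the other groups, gave 121 to 185, 20 to 45, 102 to 160, 691 to 808, 395 to 878, 27 to 405, 18 to 555, 51 to 724 and 905 to 1747.

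Of 31 list tests past the threshold 7 remained with an estimated correlation; 34 passed with fry in place of camera, 33 with quantile normalization or camera with the replicate block and 36 with FPKM as deposited. With the multipliers divided out, RPS3A (-0.0573), RPL10A (-0.0894) and EEF1A1 (-0.0144) turned in STING free and BIRC5 (0.0336) in vector. With FPKM as deposited the list test turned for ribosomal protein genes in MAVS polysomes (median -0.16) and vector (-0.20). It also turned for oxidative phosphorylation genes in MAVS polysomes (-0.22), STING free (-0.0879), MAVS free (-0.0467) and vector (0.0388). These medians are relative to genes above the highest floor in all libraries compared, while the list test compares with all other tested genes. Genes at the floor shift there by another amount than high genes, by construction. Quantile normalization turned the ribosomal median in MAVS polysomes (0.0223) and in vector (0.23).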

Other observations

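The set of TMEM-named genes in this part was chosen only after the result was seen, while the tests of predicted hydrophobic segments without such a name were written before their result was seen.

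Genes with a TMEM name were lower in polysomes of STING cells. Since the set was chosen from called genes, its values are given without p-values. Of 81 genes with a TMEM name and a mean above 5 scaled FPKM, TMEM173 itself left out, 19 were called lower and 0 higher for STING against vector. Their median was -0.467, and the difference from 2796 genes without a predicted hydrophobic segment was -0.586 to -0.479 in the 4 pairs of a STING and a vector library. Against MAVS the difference was -0.438. In the free fraction it was -0.0963, and for MAVS against vector in polysomes it was -0.0250.

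The hypothesis that mRNAs encoding a hydrophobic segment are lower in STING polysomes was tested in 987 other genes with a predicted segment and no TMEM name. The test used the libraries in which TMEM-named genes were seen to fall. Other genes already seen to fall were not left out, so it is no independent check. Of the 987 genes, 82 (8.31%) were called lower and 10 higher, against 95 (3.4%) lower and 53 higher of the 2796 genes without a segment. The median of the 987 lay 0.228 ± 0.0198 below that of the 2796 (camera adjusted p = 7.92e-05, and adjusted p = 0.00110 with an estimated correlation). With length, GC content and level removed the difference was -0.249 ± 0.0188, which fits the hypothesis. It was -0.267 to -0.227 in the 4 pairs of libraries. Quantile normalization did not turn the difference, which was then -0.251. With the multipliers divided out and no further scaling it was -0.232, and with them left in it was -0.245. These last values cannot test the scaling. A multiplier of a group or library cancels from a difference between gene sets, apart from the floor and the pseudocount. For the polysome-to-free ratio the difference was -0.195 (camera adjusted p = 0.00151), and in the free fraction it was -0.0505 (camera adjusted p = 0.693). For the ratio with MAVS against vector it was -0.0763 (camera adjusted p = 0.302). For the ratio of STING against MAVS it was -0.151, which did not pass (camera adjusted p = 0.059, and adjusted p = 0.00931 with an estimated correlation). In vector cells such genes were higher in polysomes than in the free fraction by 0.450 ± 0.0379 (camera adjusted p = 1.65e-05). These values are consistent with a lower polysome association of mRNAs with such a segment when STING is expressed, but the prediction comes from sequence alone, secreted and membrane proteins were not told apart, and PERK was not manipulated here.

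The same test for MAVS polysomes gave -0.0427 ± 0.00853 with length, GC content and level removed. That meets the criterion set, below 0 by more than 2 SE, but the SE is over genes and not over libraries. With nothing removed the difference was -0.0315 ± 0.0121 (camera adjusted p = 0.237, and adjusted p = 0.0544 with an estimated correlation). It ran from -0.0742 to -0.0181 in the 4 pairs of libraries, and 0 of the genes were called lower and 2 higher. The values therefore do not decide the question for MAVS. All SEs here are from 1000 bootstrap draws over genes, and 18 set tests were adjusted together. These include the tests of the TMEM-named set, chosen from called genes, which can lower the adjusted p-values of the 987 genes. Unadjusted, the 987 genes in STING polysomes had p = 2.2e-05 with camera and p = 0.000122 with an estimated correlation.

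The multipliers in the deposited table put MAVS polysomes 1.77 times and STING polysomes 1.88 times above vector polysomes, and MAVS free 1.555 times and STING free 1.985 times above vector free. The median of the authors' deposited ratio was 5.25 and 5.77 for vector, 5.93 and 6.19 for STING and 7.08 and 7.02 for MAVS. A change in the total amount of mRNA per fraction could not be tested from the values used here.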
